A study of Homo sapiens with 12 samples.

How the data were processed

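The libraries were made from H9 human embryonic stem cells. Per the labels' protocols, total RNA was extracted with TRIzol-LS, stranded poly(A) libraries were prepared with a TruSeq kit and 15 cycles of PCR, and they were read in paired-end mode on a MiSeq. The submitters' processing notes name STAR 2.5.3, HTSeq 0.9.1 and the genome build hg19, without their roles. The counting settings and the gene annotation are not given in the sources used here, so strand-aware counting cannot be assumed, and values of antisense, overlapping or near-identical genes, such as ALPP and ALPPL2 or members of the PRAMEF, TRIM and RFPL families, are uncertain. PCR copies were not marked by molecular identifiers, so floors cover counting error only.

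The authors deposited 1 table of 26364 genes by 12 libraries, whose name says RPKM but whose columns each sum to 1000000, so the values were treated as TPM. The test had been chosen on the assumption that the deposited unit was RPKM, and the same test applies to TPM. All 12 columns were matched to a group by name; the columns of a group carry no replicate number. Of the genes, 4597 were at 0 in every library. On 28 lines a spreadsheet had turned the symbol into a date, with 2 of the dates on more than 1 line; these stayed in the fits and are not named. Some genes that the rule would name are not reported here. TPM keeps no depth of its own, but the low values of each gene were whole multiples of 1 read. Whole reads were recovered for 100% of 21767 genes above 0, within a tolerance of 0.01, and gave depths of 8883018 to 12567835 reads per library. As a check, the gene lengths that this recovery implies had a Spearman rho of 0.829 with annotated exon lengths across 12552 genes, which are not independent replicates. At the median gene 1 read was worth 0.0607 to 0.0986 TPM, and the floor of 3 reads per library 0.182 to 0.296 TPM.

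Groups were taken from the sample titles: parental TF, NR5A1-CHIR and tt2iLGöX with 3 libraries each, and EOS-TF, EOSN1-CHIR and EOS-reset with 1 each. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Read counts of every pair within a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.75 to 28.0, so no library was counted as a repeat of another. Genes with at least 1 TPM in at least 3 libraries were tested, 15512 in all. One limma model (limma 3.58.1 in R 4.3.3, with trended and robust empirical Bayes) was fitted to log2(TPM + 1) of all 12 libraries with a mean per group, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Groups of 1 library were assumed to vary like the others. Folds against a group without a read are given as bounds at the floor. The comparisons were NR5A1-CHIR with parental TF, tt2iLGöX with parental TF and with NR5A1-CHIR, and EOS-reset with tt2iLGöX, and the difference between the CHIR effects of both lines was tested as an interaction. The same model was tested on simulated data with 200 changed genes. All genes and groups were given the same dispersion of 0.00771, and far fewer genes were changed than the real comparisons called. The rates that follow therefore need not hold for the real libraries. For NR5A1-CHIR against parental TF it recovered 83.9% of genes changed 2-fold and 95.7% of those changed 4-fold over 14408 genes, with 5.62% of calls false. For tt2iLGöX against parental TF the values were 87.1% and 95.7% over 14402 genes, with 7.57% of calls false. For tt2iLGöX against NR5A1-CHIR they were 83.5% and 90.5% over 14276 genes, with 6.90% of calls false.

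The tests, the 23 gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names NR5A1 and NR5A2, and per comparison of replicated groups the 8 largest rises and 8 largest falls with a mean of at least 5 TPM in the higher group and no overlap of the libraries. It allows every measured member of the lists of core, naive and primed pluripotency, Wnt targets, primitive streak and mesendoderm, TGF-β/Nodal targets, FGF/ERK targets and steroidogenic NR5A1 targets. From each other list it takes up to 4 members with the largest change: trophoblast, primitive endoderm, neuroectoderm, fibroblast markers, 8-cell and genome activation, DNA methylation, imprinted genes, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, cholesterol biosynthesis, p53 targets, the integrated stress response, G2/M genes and replication histones. For EOS-reset it takes the 5 largest changes in each direction. The 13 mitochondrially encoded genes, 0 of which were found by name among the genes of the table, were not analysed here. Some genes stand in more than 1 list, such as KLF17, ARGFX, CGA, DLK1, PDGFRA, SOX3, DNMT3B, DNMT3L, TDGF1 and FDXR. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which does not compare a list with other genes. Counts are also given adjusted over the list alone. List scores were compared by two-sided exact permutation tests.

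Alternatives were a pseudocount of 0.1, no filter on low values, a minimum log2 change of 1, median-ratio rescaling, quantile normalization, array weights, only the 6 libraries compared, a term for the EOS line, EOS-TF as control, and each replicate left out in turn. The line term can be estimated only through EOS-TF and EOSN1-CHIR, 1 library each, and assumes the same line difference in every condition. Chosen after seeing the data were limma-voom on the recovered reads, the line term for NR5A1-CHIR against parental TF, the line term together with rescaling, the split of the parental libraries between both contrasts, the removal of each library's trend with gene length and GC content (loess, span 0.3), the alternatives of the interaction and of EOS-TF against parental TF, and those of the EOS contrast of CHIR and TF. GC content came from an annotation of GRCh38, another build than hg19, used for gene properties only. Length was the relative gene length implied by the recovery of whole reads from the deposited values. Of the 15512 genes, 15056 had both, with GC content found by symbol for 14586 and by an older or newer symbol for 470. The covariance that shared libraries bring was simulated 20 times with unchanged groups. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.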

Results

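Poly(A) RNA was measured in 12 libraries of H9 human embryonic stem cells, an established line that grows in the primed state of pluripotency. The study asked whether overexpression of NR5A1, a nuclear receptor of steroidogenic tissues and a paralog of the pluripotency factor NR5A2, holds these cells between primed and naive pluripotency. Parental cells kept with doxycycline in mTeSR1 medium gave 3 libraries (parental TF). Cells overexpressing NR5A1 with doxycycline, in a custom mTeSR1 without FGF2 and TGF-β and with 3 µM of the GSK3 inhibitor CHIR99021, gave 3 libraries (NR5A1-CHIR). A line labelled EOS and carrying NR5A1 gave 3 libraries without doxycycline in the condition named tt2iLGöX, which the labels call naive. The same EOS background gave 1 library each in the TF condition (EOS-TF), in the CHIR condition with NR5A1 (EOSN1-CHIR) and from tt2iLGöX-cultured cells called EOS-reset. The tables held 8883018 to 12567835 reads per library, and 15512 genes were tested. Levels are in TPM, transcript abundance scaled to a total of 1000000 per library, as mean ± SD of 3 libraries. Fold changes are differences on the log2(TPM + 1) scale ± SE, 3 libraries against 3, and understate the change of genes expressed at low levels.

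NR5A1 itself followed the labels. It stood at 0.346 ± 0.0771 TPM in parental TF and 44.9 ± 4.69 TPM in NR5A1-CHIR, a rise of 5.09 ± 0.24 (adjusted p = 4.96e-08, limma). The single EOS-TF and EOSN1-CHIR libraries held 0.192 and 77.9 TPM. Without doxycycline, the tt2iLGöX libraries held 4.03, 4.07 and 1.54 TPM, from 53, 61 and 22 reads, and EOS-reset 0.0688 TPM from 1 read. NR5A1 was 1.58 ± 0.24 above parental TF in the tt2iLGöX libraries and fell by 3.51 between NR5A1-CHIR and tt2iLGöX. NR5A2 was lower in NR5A1-CHIR (-0.98 ± 0.21) and in tt2iLGöX (-0.49 ± 0.21) than in parental TF. The second of these calls was lost under median-ratio rescaling, among other settings, and the difference between tt2iLGöX and NR5A1-CHIR, 0.49 ± 0.21, did not pass the test.

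The first comparison, of NR5A1-CHIR with parental TF, asked what the receptor and the CHIR medium changed together. Because the receptor, the inhibitor and the medium changed at once, their effects are not separated. The largest rise on the log2(TPM + 1) scale was that of DPPA5. This germ cell and naive marker went from 3.35 ± 0.510 to 879 ± 85.7 TPM (7.66 ± 0.10), and NLRP7, a maternal-effect gene, from 1.77 ± 0.304 to 97.5 ± 15.5 TPM (5.14 ± 0.14). ZIC2, a transcription factor of primed cells and neuroectoderm, went from 64.2 ± 10.2 to 0.862 ± 0.670 TPM (-5.17 ± 0.22). DUSP6, a phosphatase induced by ERK signalling, went from 264 ± 4.20 to 6.87 ± 1.44 TPM (-5.09 ± 0.15). The other large rises were KRBOX1 (7.09 ± 0.18), RHOXF1P1 (5.87 ± 0.39), ZNF560 (5.80 ± 0.11), the cytokine gene IL18 (5.49 ± 0.20), and LOC100506790, which had no read in parental TF and was at least 18.5-fold higher at 33.0 ± 15.3 TPM. The other large falls were the Wnt antagonist SFRP1 (-5.46 ± 0.10), D21S2088E (-5.08 ± 0.15), RAB3C (-4.94 ± 0.39), RGS5 (-4.85 ± 0.18), the vasoactive peptide gene ADM (-4.73 ± 0.26) and FAM65B (-4.70 ± 0.17). With NR5A1 these are the 8 largest rises and 8 largest falls that the naming rule selects; their highest adjusted p was 6.17e-06, and none lost its call or turned under 14 alternative settings. LOC100506790 lacked a length or GC value, so the setting with that trend removed holds no value for it.

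Of the 29 naive pluripotency genes tested, 22 rose and 1 fell in NR5A1-CHIR (the same adjusted over the list alone, camera adjusted p = 8.52e-09, adjusted p = 0.313 with an estimated correlation). KLF4 (3.91 ± 0.23), TFCP2L1 (2.05 ± 0.19) and KLF5 (1.91 ± 0.19), transcription factors of the naive network, rose from levels of 0.801 to 1.67 TPM. KHDC3L (4.72), FGF4 (4.27), DNMT3L (3.72), VENTX (3.71), DPPA2 (3.05) and DPPA3 (2.41) rose as well, and the 1 gene that fell was NR5A2. KLF17 (0.44), OLAH (-0.12), FAM151A (-0.05) and ST6GAL1 (0.05) did not pass the test. Of 27 primed genes, 21 fell and 4 rose (the same adjusted over the list alone, camera adjusted p = 0.000178, adjusted p = 0.313 with an estimated correlation). ZIC5 (-4.38), SALL1 (-3.46), OTX2 (-3.07), HMX2 (-3.09) and NLGN4X (-2.87) fell several times over, whereas the surface antigen genes CD24 (-0.64) and THY1 (-0.74, not past the test with a pseudocount of 0.1) fell less. Primed genes that rose included the de novo methyltransferase gene DNMT3B (1.77 ± 0.15), NEFL (1.24) and SFRP2 (0.95). Of 15 core pluripotency genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.00143, adjusted p = 0.313 with an estimated correlation). UTF1 (3.74 ± 0.25), PRDM14 (2.59 ± 0.15), GAL (1.99), NANOG (1.03 ± 0.12) and POU5F1 (0.63 ± 0.09) rose, and LIN28A (-0.47) and SOX2 (-0.48 ± 0.11) fell, SOX2 not past the test with a line term and median-ratio rescaling together.

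Direct Wnt target genes went both ways under the GSK3 inhibitor. Of 12 tested, 7 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.250, adjusted p = 0.619 with an estimated correlation). The feedback gene AXIN2 (2.97 ± 0.12), the β-catenin partner TCF7 (2.65 ± 0.17), BAMBI (1.92) and CCND1 (1.17) rose, and the retinoic acid hydroxylase gene CYP26A1 (-3.36), APCDD1 (-1.89) and SP8 (-1.77) fell. Of 13 primitive streak and mesendoderm genes tested, 6 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.515, adjusted p = 0.713 with an estimated correlation), among them FGF8 (2.18) and WNT3 (1.69) upward and CER1 (-2.41) downward, while T, the brachyury gene, reached only 1.42 ± 0.329 TPM. In medium without TGF-β, 8 of 13 TGF-β/Nodal targets rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.00754, adjusted p = 0.463 with an estimated correlation). NODAL went from 4.41 ± 0.0525 to 119.8 ± 22.1 TPM (4.46 ± 0.20), and GDF3 (3.45 ± 0.21), the Nodal antagonist genes LEFTY2 (2.41) and LEFTY1 (1.95), and SKIL (1.99) rose, while TGFBI (-1.97) fell. Of 19 FGF/ERK targets, 7 rose and 7 fell in medium without FGF2 (8 and 7 adjusted over the list alone, camera adjusted p = 0.836, adjusted p = 0.899 with an estimated correlation). DUSP6, PHLDA1 (-2.22) and DUSP4 (-1.98) fell, FOS (1.75), FOSL1 (1.55) and DUSP5 (1.06) rose, and SPRY4 (-0.06) and ETV5 (0.34) did not pass the test.

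Steroidogenic genes, the classical targets of NR5A1 in adrenal and gonad, changed in part. Of 27 listed, 11 were expressed highly enough to be tested, of which 5 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.250, adjusted p = 0.463 with an estimated correlation). STAR, which moves cholesterol into mitochondria, went from 3.14 ± 0.125 to 11.9 ± 1.56 TPM (1.64 ± 0.15), and SCARB1 (0.85), POR (0.77) and FDXR (0.73) rose. CYP11A1, the side-chain cleavage enzyme gene, stood at 8.60 ± 0.156 and 4.91 ± 0.689 TPM (-0.71), a fall that did not pass the test under median-ratio rescaling or with any 1 of the 6 libraries left out. Of 15 genes of the 8-cell stage and of genome activation, 9 rose and 0 fell (the same adjusted over the list alone, camera adjusted p = 0.00422, adjusted p = 0.483 with an estimated correlation). All but CCNA1 (3.10 ± 0.17) stayed low: TRIM43 and KDM4E, without a read in parental TF, reached 2.25 ± 1.12 and 2.07 ± 0.610 TPM. Of 15 DNA methylation genes, 9 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00754, adjusted p = 0.463 with an estimated correlation), with DNMT3L, the imprint guardian ZFP57 (3.40 ± 0.14), DNMT3B and UHRF1 (1.25) as the largest rises. In the EOS pair the list median was -0.32 against 0.60. The list score nevertheless went from 5.05 in EOS-TF to 5.19 in EOSN1-CHIR, with 2 members higher and 0 lower by a log2 difference of 1. Of 19 imprinted genes, 9 rose and 6 fell (the same adjusted over the list alone, camera adjusted p = 0.357, adjusted p = 0.463 with an estimated correlation). The largest rises were DLK1 (4.29 ± 0.18), CDKN1C (2.49 ± 0.18), PHLDA2 (2.34 ± 0.15) and PEG3, which had no read in parental TF and was at least 222-fold higher at 17.0 ± 10.4 TPM.

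No list of markers of other cell types passed camera, whereas fry passed the fibroblast list (adjusted p = 0.000128) and the primitive endoderm list (adjusted p = 0.0112), both downward. Of 18 trophoblast markers, 4 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.515, adjusted p = 0.893 with an estimated correlation), with TFAP2C, also a naive factor, the largest rise (2.76 ± 0.17). Of 12 primitive endoderm markers, 2 rose, PDGFRA (1.54) among them, and 4 fell, among them COL4A2 (-1.16) and COL4A1 (-1.08) (the same adjusted over the list alone, camera adjusted p = 0.515, adjusted p = 0.713 with an estimated correlation). Of 6 neuroectoderm markers tested, 2 rose and 2 fell, the latter SOX3 (-1.59) and MAP2 (-1.35) (3 and 2 adjusted over the list alone, camera adjusted p = 0.883, adjusted p = 0.899 with an estimated correlation). Of 13 fibroblast markers, 2 rose and 7 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.171, adjusted p = 0.463 with an estimated correlation): TAGLN fell most (-3.73 ± 0.26), whereas COL1A1 rose (2.10 ± 0.19). With limma and Benjamini-Hochberg adjustment over all 15512 genes, 4128 genes rose and 4876 fell, 1327 and 1713 of them by a log2 change of at least 1. Median-ratio rescaling turned this balance, to 4693 higher and 4371 lower, and removal of the length and GC trend gave 4552 and 4443.

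**Figure D1:**
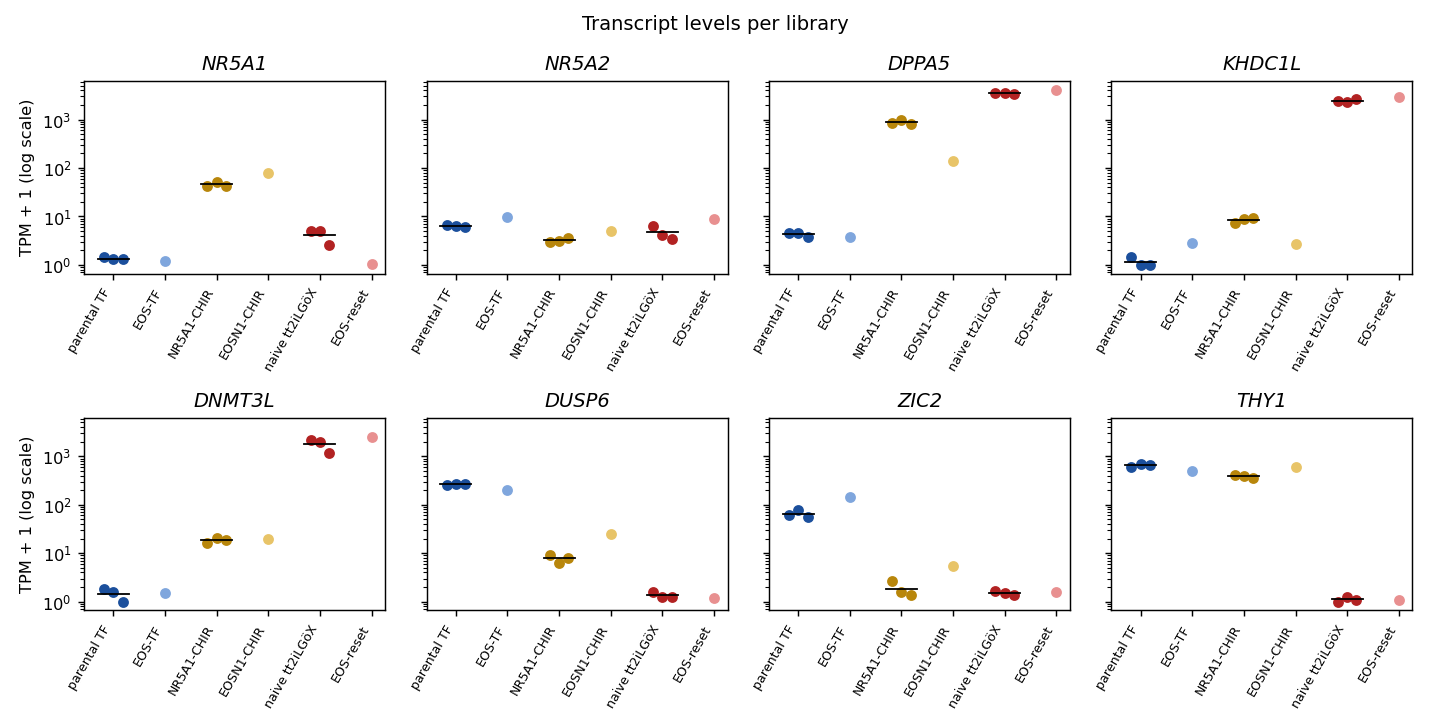
TPM + 1 on a log axis of NR5A1, NR5A2, DPPA5, KHDC1L, DNMT3L, DUSP6, ZIC2 and THY1 in the 12 libraries, 1 point per library in the 6 groups, with a black bar at the mean of each group of 3. DPPA5 stood at 3.35, 879 and 3500.0 TPM in parental TF, NR5A1-CHIR and tt2iLGöX, and THY1 at 645, 386 and 0.116 TPM.

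The EOS background gave the same contrast with 1 library on each side and so without a replicate check. Between EOS-TF and EOSN1-CHIR, DPPA5 went from 2.70 to 137 TPM, NLRP7 from 1.91 to 89.5 TPM and NODAL from 8.25 to 208 TPM, while ZIC2 went from 141 to 4.44 TPM and DUSP6 from 199 to 24.1 TPM. Of the 4128 genes that rose in NR5A1-CHIR, 64.6% were higher in EOSN1-CHIR than in EOS-TF, and of the 4876 that fell, 80.6% were lower. After median-ratio rescaling these shares were 71.1% and 75.5%, so the gap between rises and falls depended in part on library scaling. Across all genes tested, which are not independent replicates, the log2 differences of both contrasts had a Pearson r of 0.622 and a Spearman rho of 0.497.

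The second comparison, of tt2iLGöX with parental TF, asked how the naive libraries differ from primed cells. The culture condition, the line, the NR5A1 construct and doxycycline differed at once, so their effects are not separated, those on FGF/ERK targets included. KHDC1L, a gene of the early embryo, went from 0.142 ± 0.245 to 2446 ± 175 TPM (11.08 ± 0.15), NLRP7 to 4463 ± 593 TPM (10.65 ± 0.14), the alkaline phosphatase gene ALPPL2 to 2973 ± 1456 TPM (10.64 ± 0.29) and DNMT3L, a cofactor of de novo methylation, to 1781 ± 539 TPM (10.25 ± 0.27). THY1 went from 645 ± 51.7 to 0.116 ± 0.131 TPM (-9.18 ± 0.11), and SFRP2 from 250.5 ± 21.7 TPM to no read, which was at least 757-fold lower with 3 reads per library as the floor. The other largest rises were DPPA5 (9.66 ± 0.10), KHDC3L (9.11 ± 0.15), the glutathione peroxidase gene GPX2 (7.50 ± 0.24) and FGF4 (7.45 ± 0.20). The other largest falls were PTPRZ1 (-7.98 ± 0.09), LINC00458 (-7.79 ± 0.28), DUSP6 (-7.62 ± 0.15), the tryptophan-degrading enzyme gene IDO1 (-7.28 ± 0.12), RARRES2 (-7.23 ± 0.16) and ID3 (-6.69 ± 0.17), a target of BMP signalling. The highest adjusted p of these 16 was 9.40e-09.

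Of the 29 naive genes, 28 rose in tt2iLGöX and 1, NR5A2, fell (the same adjusted over the list alone, camera adjusted p = 4.07e-14, adjusted p = 0.102 with an estimated correlation). KLF17 (3.74 ± 0.23), DPPA3 (7.18 ± 0.30), SUSD2 (5.74 ± 0.14), a surface marker of naive cells, KLF4 (5.96 ± 0.23), KLF5 (5.80 ± 0.19), TFCP2L1 (4.02 ± 0.19) and OLAH (7.31 ± 0.19) rose. ZNF729 and TRIM60, without a read in parental TF, were at least 945-fold and 347-fold higher. Of 27 primed genes, 25 fell and 0 rose (the same adjusted over the list alone, camera adjusted p = 4.79e-10, adjusted p = 0.102 with an estimated correlation). Among them were ZIC2 (-5.44 ± 0.22), USP44 (-5.19 ± 0.16), CRABP1 (-5.00 ± 0.36), FZD7 (-4.76 ± 0.19), the intermediate filament gene VIM (-4.75 ± 0.18) and CDH2 (-4.65 ± 0.20). DNMT3B was among those that did not pass the test (0.29), but it was lower with a line term (-1.11). Core genes went both ways, 6 of 15 higher and 8 lower (the same adjusted over the list alone, camera adjusted p = 0.683, adjusted p = 0.878 with an estimated correlation): UTF1 (4.72), PRDM14 (2.56) and NANOG (1.30) rose, and FOXD3 (-3.14), L1TD1 (-3.04), TERF1 (-2.77) and SOX2 (-1.40) fell. Targets of FGF/ERK signalling fell together, 17 of 19 with 0 higher (the same adjusted over the list alone, camera adjusted p = 2.11e-06, adjusted p = 0.274 with an estimated correlation), including ETV1 (-5.75), SPRY4 (-5.53), ETV5 (-4.02) and SPRED1 (-3.17). Wnt targets rose in 8 cases of 12 and fell in 2 (the same adjusted over the list alone, camera adjusted p = 0.121, adjusted p = 0.605 with an estimated correlation), with SP8 (3.29) and AXIN2 (1.87) up and CYP26A1 (-3.21) down. Of the TGF-β/Nodal targets, 6 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.208, adjusted p = 0.761 with an estimated correlation), with NODAL (4.72) and GDF3 (4.39) up, and LEFTY1 (-0.27) and LEFTY2 (-0.51) not past the test. Mesendoderm genes rose in 6 cases and fell in 6 of 13 (the same adjusted over the list alone, camera adjusted p = 0.969, adjusted p = 0.972 with an estimated correlation), with WNT3 (3.69) up and KDR (-4.75) down. Of the 11 steroidogenic genes tested, 5 rose and 4 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.618, adjusted p = 0.761 with an estimated correlation). A line term gave 4 higher and 4 lower TGF-β/Nodal targets, with the list median going from 0.47 to -0.30, and 5 and 2 Wnt targets, 5 and 4 mesendoderm genes and 3 and 3 steroidogenic genes.

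Genes of the 8-cell stage rose in 14 of 15 cases, with 0 lower (15 and 0 adjusted over the list alone, camera adjusted p = 0.000193, adjusted p = 0.583 with an estimated correlation). Among them were CCNA1 (3.97), TPRX1, which had no read in parental TF and reached 5.41 ± 1.22 TPM, and ZSCAN4 (2.46). Imprinted genes rose in 10 of 19 cases and fell in 5 (the same adjusted over the list alone, camera adjusted p = 0.208, adjusted p = 0.474 with an estimated correlation). The long noncoding RNAs MEG3 (7.41 ± 0.20) and H19 (6.22 ± 0.53) reached 171 ± 15.5 and 171 ± 151 TPM, with H19 at 343, 63.2 and 106 TPM in the 3 libraries. Of 15 DNA methylation genes, 11 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.00163, adjusted p = 0.415 with an estimated correlation), including TET1 (2.57 ± 0.12). With a line term these splits became 5 and 4 for DNA methylation and 5 and 8 for imprinted genes. Of 18 trophoblast markers, 10 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.235, adjusted p = 0.849 with an estimated correlation), and library 1 stood apart with a list score of 4.09 against 3.00 and 3.09 in the others. GATA3 (3.01 ± 0.56) and GATA2 (3.34 ± 0.45) varied among the tt2iLGöX libraries, at 11.9 ± 11.8 and 11.4 ± 9.18 TPM. Of 12 primitive endoderm markers, 5 rose and 6 fell (the same adjusted over the list alone, camera adjusted p = 0.863, adjusted p = 0.931 with an estimated correlation), with HNF4A at 8.64 ± 0.945 TPM (3.22 ± 0.14). Neuroectoderm markers split 3 and 3, or 1 higher and 3 lower with a line term (the same adjusted over the list alone, camera adjusted p = 0.972, adjusted p = 0.972 with an estimated correlation without it). Of 13 fibroblast markers, 10 fell while 2 rose (the same adjusted over the list alone, camera adjusted p = 0.0630, adjusted p = 0.415 with an estimated correlation). In all, 5489 genes rose and 6078 fell (limma), 2853 and 3221 of them by a log2 change of at least 1. The rho of the change with GC content across genes was 0.317. Removal of the length and GC trend turned the balance, to 5565 higher and 5436 lower. Of the calls with both values, 81.0% then stayed in the same direction. The tt2iLGöX libraries are of the EOS background and parental TF is not, and with a line term 3113 genes rose and 5512 fell, of which 2848 and 4563 were called alike without it and 158 in the opposite direction. That term rests on the single EOS-TF and EOSN1-CHIR libraries. It assumes the same line difference in every condition, which the interaction test below did not bear out for part of the genes. With the line term the median log2 difference of all genes was -0.21, and with median-ratio rescaling added it was 0.02. Line-term splits of lists in the tt2iLGöX comparisons are given without rescaling, so they include this shift of all genes. Against the single EOS-TF library, tt2iLGöX had 3051 genes higher and 5718 lower, 34.8% higher with a median log2 difference of -0.24 over all genes, and after median-ratio rescaling 51.4% were higher with a median of 0.01.

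The third comparison, of tt2iLGöX with NR5A1-CHIR, asked what still separated the NR5A1-CHIR cells from the naive libraries. Here too the culture condition, the line and doxycycline differed at once, so their effects are not separated. KHDC1L (8.19 ± 0.15), ALPPL2 (8.16 ± 0.29), the thioesterase gene OLAH (7.44 ± 0.19) and H19 (6.94 ± 0.53) were higher in tt2iLGöX. THY1 (-8.44 ± 0.11), PTPRZ1 (-7.06 ± 0.09) and KRBOX1 (-6.74 ± 0.18) were lower, and SFRP2, at 489 ± 90.9 TPM in NR5A1-CHIR and without a read in tt2iLGöX, was at least 1479-fold lower. The other largest rises were MEG3 (6.57 ± 0.20), DNMT3L (6.53 ± 0.27), the synaptonemal complex gene SYCP3 (6.47 ± 0.23) and TKTL1 (6.23 ± 0.47), which varied widely at 109.7 ± 91.3 TPM. Other large falls included VSNL1 (-6.70 ± 0.23), the lysosomal lipase gene LIPA (-6.37 ± 0.10) and LINC00458 (-6.31 ± 0.28). The highest adjusted p of the 8 largest rises and 8 largest falls under the rule was 7.07e-06.

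Of 29 naive genes, 26 were higher in tt2iLGöX and 1, DPPA2 (-1.83 ± 0.10), was lower (27 and 1 adjusted over the list alone, camera adjusted p = 1.30e-12, adjusted p = 0.131 with an estimated correlation). KLF5 (3.89), SUSD2 (4.07), DPPA3 (4.76), KLF4 (2.04) and DPPA5 (1.996) rose further, and VENTX (0.37) did not pass the test. KLF17 (3.30), whose change from parental TF to NR5A1-CHIR had not passed the test, was higher as well. Of 27 primed genes, 23 were lower and 1, OTX2 (1.18 ± 0.19), was higher (the same adjusted over the list alone, camera adjusted p = 9.03e-09, adjusted p = 0.131 with an estimated correlation). USP44 (-5.09), CD24 (-3.71), FZD7 (-3.73) and DNMT3B (-1.48) were lower, and ZIC2 (-0.26), SALL1 (0.36) and HMX2 (-0.07), already near 1 TPM or below in NR5A1-CHIR, did not pass. FGF/ERK targets were lower in 18 of 19 cases, with 0 higher (the same adjusted over the list alone, camera adjusted p = 9.03e-09, adjusted p = 0.145 with an estimated correlation), among them SPRY4 (-5.47 ± 0.14), ETV1 (-5.45 ± 0.12), ETV5 (-4.36 ± 0.14), EPHA2 (-3.82) and MYC (-2.50). Of 15 core genes, 9 were lower and 1 higher (the same adjusted over the list alone, camera adjusted p = 0.0105, adjusted p = 0.392 with an estimated correlation), with FOXD3 (-3.86), TERF1 (-3.51), L1TD1 (-3.25) and POU5F1 (-1.36) down. Wnt targets split 4 higher and 5 lower of 12 (the same adjusted over the list alone, camera adjusted p = 0.994, adjusted p = 0.997 with an estimated correlation), as AXIN2 (-1.09), TCF7 (-1.09) and BAMBI (-1.11) fell and SP8 (5.06 ± 0.21) rose. TGF-β/Nodal targets split 5 and 5 of 13 (the same adjusted over the list alone, camera adjusted p = 0.994, adjusted p = 0.997 with an estimated correlation): SKIL (-2.95), LEFTY2 (-2.92) and LEFTY1 (-2.22) fell, and NODAL (0.26) did not pass.

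Mesendoderm genes split 4 higher and 3 lower of 13 (the same adjusted over the list alone, camera adjusted p = 0.994, adjusted p = 0.997 with an estimated correlation), with KDR (-4.54 ± 0.21) and PDGFRA (-2.17 ± 0.24) down. Of 11 steroidogenic genes, 3 were higher and 3 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.994, adjusted p = 0.997 with an estimated correlation), with SOAT1 (3.45) up and STAR (-2.09) down. Genes of the 8-cell stage were higher in 8 of 15 cases and lower in 0 (the same adjusted over the list alone, camera adjusted p = 0.0142, adjusted p = 0.729 with an estimated correlation). A line term turned the balance of mesendoderm genes, to 2 higher and 5 lower with a median of -0.82, and gave 2 and 6 TGF-β/Nodal targets and 2 and 5 Wnt targets. In all, 5056 genes were higher and 4964 lower (limma), 1955 and 2049 of them by a log2 change of at least 1. The balance turned with median-ratio rescaling, to 5001 and 5078, and with limma-voom, to 4676 and 5496. Removal of the length and GC trend gave 4876 higher and 4742 lower. Of the calls with both values, 82.2% then stayed in the same direction, and the rho with GC content had been 0.251. With a line term 2799 were higher and 4573 lower, of which 2452 and 3540 were called alike without it and 159 in the opposite direction. The median log2 difference of all genes was -0.15 with that term and -0.003 with rescaling added, a shift that the line-term list splits include. Against the single EOSN1-CHIR library 2960 were higher and 4488 lower, a share higher of 39.7% that became 50.7% after median-ratio rescaling.

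**Figure D2:**
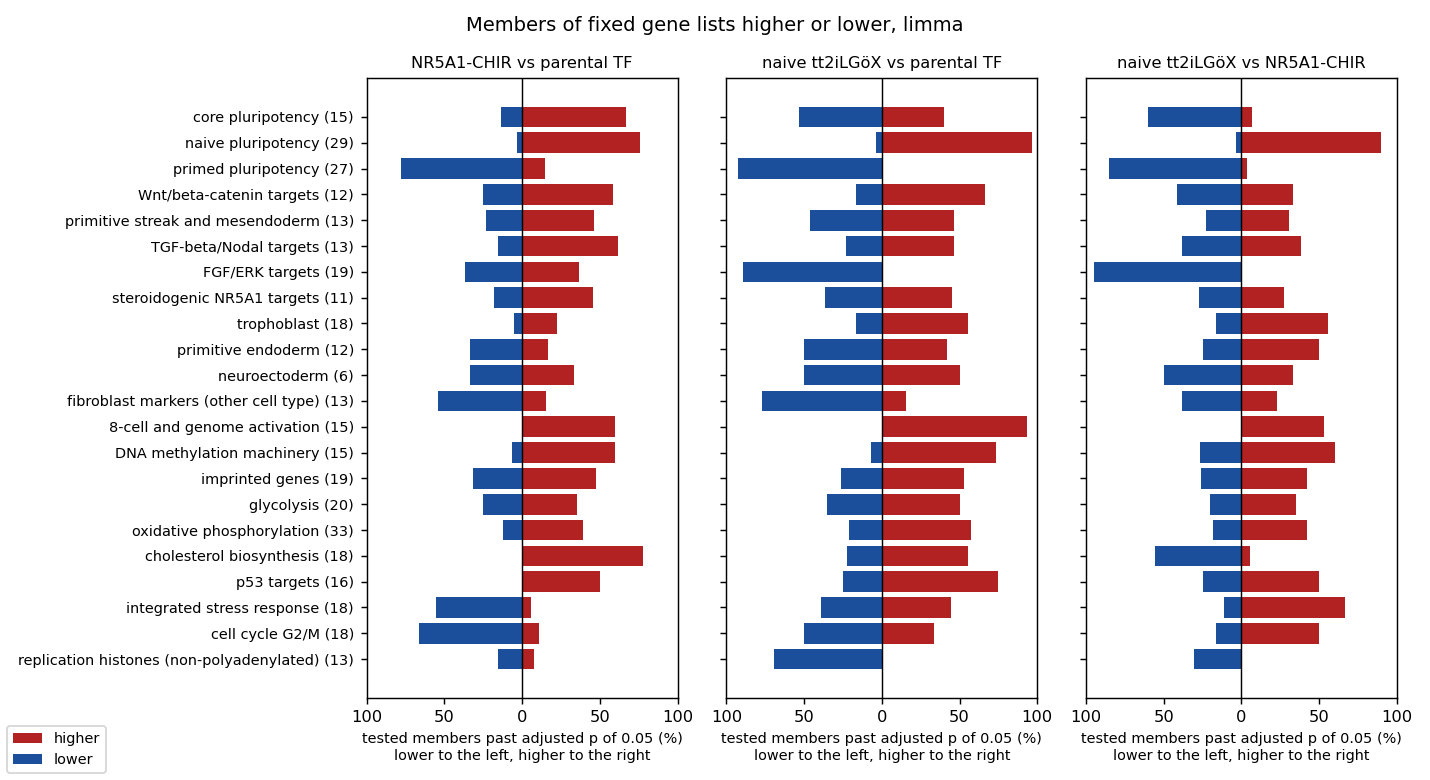
Percent of the tested members of 22 gene lists that were higher or lower, in NR5A1-CHIR against parental TF, tt2iLGöX against parental TF and tt2iLGöX against NR5A1-CHIR (limma). In tt2iLGöX against parental TF, 28 of 29 naive genes were higher and 25 of 27 primed genes lower.

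The position of NR5A1-CHIR between both ends was measured with list scores, each the mean log2(TPM + 1) of a list's tested members in a library. The naive score was 1.32 ± 0.09 in parental TF, 3.38 ± 0.08 in NR5A1-CHIR and 7.04 ± 0.20 in tt2iLGöX (SD, n = 3 each), so that NR5A1-CHIR lay 36.0 ± 1.36% of the way from parental TF to tt2iLGöX. The primed score was 6.18 ± 0.09, 4.87 ± 0.09 and 2.35 ± 0.08, which put NR5A1-CHIR at 34.1 ± 2.28% of the way. The SD of a position is that of the 3 NR5A1-CHIR scores, with both ends held at their means. It leaves out the spread of parental TF and tt2iLGöX and so understates the uncertainty of the position. In the EOS background the naive score was 1.43 in EOS-TF, 3.22 in EOSN1-CHIR and 7.22 in EOS-reset, and the primed score 6.66, 5.44 and 2.14; EOSN1-CHIR lay 32.0% and 28.3% of the way from EOS-TF to the tt2iLGöX mean. The libraries of parental TF, NR5A1-CHIR and tt2iLGöX did not overlap in either score, and each pairwise two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 can give. Core genes scored 6.59 ± 0.10, 7.45 ± 0.02 and 6.43 ± 0.08, highest in NR5A1-CHIR. FGF/ERK targets scored 4.32 ± 0.14, 4.07 ± 0.10 and 1.64 ± 0.05, at 9.36 ± 3.65% of the way. A position on these scores does not separate cell state from culture condition.

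**Figure D3:**
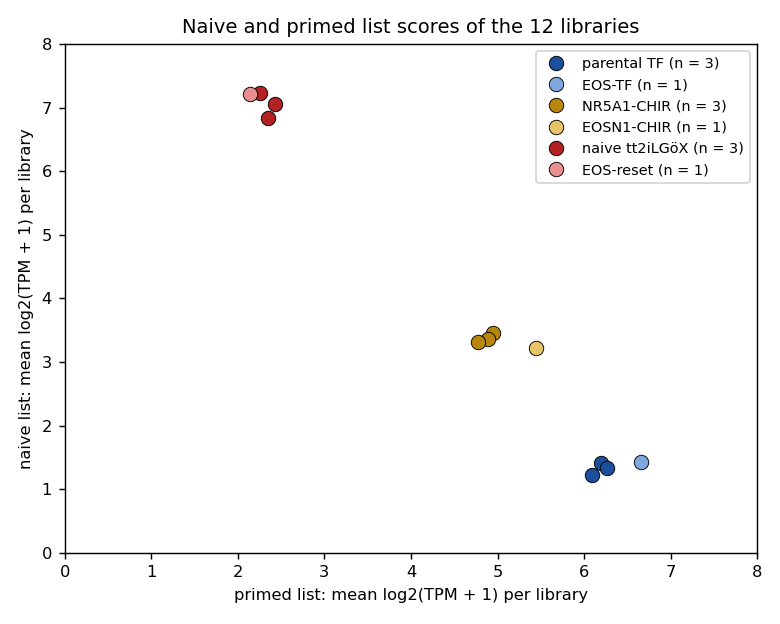
Naive score against primed score, each the mean log2(TPM + 1) of the tested list members, 1 point per library for the 12 libraries in 6 groups. The NR5A1-CHIR libraries lay between parental TF and tt2iLGöX on both axes, with mean naive scores of 1.32, 3.38 and 7.04 in that order.

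Both groups, each against parental TF, shared 2866 higher genes, DPPA5, NLRP7, NODAL and KLF4 among them, and 3642 lower genes, ZIC2, DUSP6, VIM and SALL1 among them, while 480 genes were higher in NR5A1-CHIR and lower in tt2iLGöX and 409 the reverse. Independent lists of these sizes would share 1461 higher and 1911 lower genes. The covariance of the fold changes was 0.781, against 0.0198 from the shared controls alone in simulation, with a Pearson r of 0.605 against a simulated 0.502. The simulated groups hold no changes, so the r values are not comparable. With the parental libraries split so that no library served both contrasts, a test chosen after the overlap was seen, the 6 possible splits shared 1801 to 2412 higher and 2512 to 3018 lower genes. Independent lists would then share 876.8 to 1097 and 1174 to 1443, and r was 0.566 to 0.595. With EOS-TF in place of parental TF as the control of tt2iLGöX, 1387 genes were higher in both and 2743 lower in both, where independent lists would share 811.9 and 1797, with r 0.421. Another 911 were then higher in NR5A1-CHIR and lower in tt2iLGöX, and 453 the reverse.

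The last comparison set EOS-reset, a naive line without the NR5A1 label, beside the tt2iLGöX libraries. Naive genes were expressed in both: KHDC1L at 2918 and 2446 ± 175 TPM, DPPA5 at 4119.9 and 3500.0 ± 88.6 TPM, and KLF17 at 15.1 and 13.3 ± 4.68 TPM. With 1 library against 3 and the spread borrowed from the other groups, 3 genes passed the test (limma), and 846 had an unadjusted p under 0.05. RBP5, a retinol-binding protein gene, stood at 8.30 ± 2.06 TPM in tt2iLGöX and had no read in EOS-reset, at least 12.2-fold lower (adjusted p = 0.00389). MIR3674, also without a read there, was at 5.39 ± 1.96 TPM (adjusted p = 0.0157), below the 9.39 TPM that 3 reads of so short a gene are worth in EOS-reset, so no fold is given. The third, MIR6768, named after its values were seen, rested on 1 read in EOS-reset and 0 in tt2iLGöX, so no difference is claimed. Among unchanged genes a share of 0.05 would have an unadjusted p under 0.05, so the number of such genes was near that without any difference. No member of the 22 lists passed over all genes, and adjusted over the list alone 1 primed, 1 steroidogenic and 2 trophoblast genes were lower. Camera with its preset correlation passed 7 lists. Higher in EOS-reset were oxidative phosphorylation (adjusted p = 1.57e-06), naive (0.00226), G2/M (0.00226) and 8-cell genes (0.0105). Lower were cholesterol (0.0146), trophoblast (0.0276) and FGF/ERK genes (0.0279). With an estimated correlation the adjusted p was 0.247 for oxidative phosphorylation and 0.618 for the other 6, and with fry 0 lists passed. NR5A1 (-1.91) and VIM (-1.58) were lower in EOS-reset without passing the test. Leaving out tt2iLGöX library 1 raised the count of genes past the test to 68 and library 3 to 14, while voom on the recovered reads gave 0.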

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

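The interaction test, the contrast of EOS-TF with parental TF and their alternatives, the test of reads shared with NR5A2, and the tests of other splits were chosen only after the results were seen.

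The change from parental TF to NR5A1-CHIR was set against the change from EOS-TF to EOSN1-CHIR, 1 library each, as an interaction in the limma model. The EOS side has no replicate, and its spread was taken from the replicated groups. For 1513 of 15512 genes the change was more positive in the other line and for 1168 more positive in the EOS line. Rescaling gave 1362 and 1289, and removal of the length and GC trend turned the balance, to 1180 and 1314, 47.3% in place of 56.4% more positive in the other line. In the limma test, 5160 genes had an unadjusted p under 0.05. Without parental TF library 3 the counts past adjustment were 938 and 763, and without NR5A1-CHIR library 2 the first was 947. Of the genes that the rule names for NR5A1-CHIR against parental TF, 46 differed, and values are given here as the log2 effect in the other line minus that in the EOS line. Naive genes rose more in the other line at KHDC1L (2.97, from effects of 2.90 and -0.07), DPPA5 (2.44, from 7.66 and 5.22) and KHDC3L (2.23), and less at DPPA2 (-1.20). Of core genes, PRDM14 (1.71), FOXD3 (1.55) and TERF1 (0.79) differed. Of primed genes, DNMT3B (1.85), B3GAT1 (1.36) and SALL2 (1.06) were more positive in the other line, and NLGN4X (-2.27), CYTL1 (-1.95), HMX2 (-1.15) and THY1 (-0.999) more negative. DUSP6 fell more in the other line (-2.10, from -5.09 and -2.99), and FOS (1.35), EPHA2 (1.35) and IL17RD (1.04) were more positive there, as were AXIN2 (0.82) and CER1 (2.11). GDF3 (-1.73), KDR (-1.57) and SNAI2 (-1.40) were more negative there. The sterol enzyme genes MVK (1.53), LSS (1.51) and NSDHL (0.65) were more positive in the other line. They are part of 8 of 18 cholesterol genes with a more positive and 0 with a more negative effect there. The stress response genes CHAC1 (-2.93, from -1.61 and 1.32), VLDLR (-2.15), ATF3 (-2.07) and ASNS (-1.77) were lower there after CHIR and not in the EOS line. The fall of CHAC1 did not pass with a line term. Of the 18 genes of this response, 11 had a more negative and 1 a more positive effect. DNA methylation genes differed in 7 of 15 cases, all more positive, including UHRF1 (1.63, from 1.25 and -0.38) and ZFP57 (1.85). Imprinted genes differed at DLK1 (3.70, from 4.29 and 0.59), PHLDA2 (2.13) and CDKN1C (1.29). The remaining values were KRBOX1 3.82, COL1A1 1.54, APOA1 1.37, CCNA1 1.32, ALDOA 1.18, CDK1 -0.79, D21S2088E -1.46, FAM65B -1.70, RGS5 -2.12 and GABRP -2.96.

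Median-ratio rescaling left 93.0% of the 2681 interaction calls in place with the same direction, which argues against library scaling as the whole cause. Removing each library's trend with gene length and GC content left 69.2% in place, more than the 50% that had been set in advance, and argues against such a bias as the whole cause. The rho of the interaction with GC content across genes was 0.306 before the trend was removed, so a contribution to the other calls is not excluded. A difference between the lines is open and untested, as is anything that goes with the single EOS libraries, since each EOS condition has 1 library.

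A step earlier, EOS-TF had 4295 genes higher and 2410 lower than parental TF, 2154 and 838 of them by a log2 change of at least 1. This is a difference between 1 library and 3, and leaving out 1 parental library gave 3645 to 4051 higher and 1979 to 2056 lower. The median-ratio factor of EOS-TF was 1.20, the highest of the 12, and rescaling gave 3232 higher and 3641 lower, 47.0% higher in place of 64.1%, with the median log2 difference of all genes going from 0.10 to -0.06. Rescaling left 84.1% of the calls in place with the same direction and removal of the length and GC trend, with 2699 higher and 3141 lower, 63.1%, which argues against each as the whole cause. DLK1 (3.76) at 0.606 and 20.7 TPM, DNMT3B (2.10) at 476 and 2028 TPM, and RGS5 (-2.20) at 55.2 and 11.1 TPM in parental TF and EOS-TF differed, and a biological difference of the lines remains untested.

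NR5A1 reads in the tt2iLGöX libraries, which are labelled as without doxycycline, were the third pattern. The ratio of NR5A1 to NR5A2 was 0.739, 1.26 and 0.619 in these libraries and 0.00893 in EOS-reset, where 1 read allows a ratio of up to 0.0498 (exact Poisson, 95%), which argues against reads shared with NR5A2. A remainder of NR5A1-CHIR cells would bring their other transcripts: 29 genes of at least 50 TPM in EOSN1-CHIR and under 1% of that in EOS-reset stood at medians of 0.445%, 0.704% and 0.672% of the EOSN1-CHIR level, with a highest upper quartile of 1.48%, while NR5A1 stood at 5.17%, 5.23% and 1.98%. In the third library 4 of the 29 genes reached the share of NR5A1, in the others 0, so carry-over of cells is argued against as the whole source. A candidate source that stays open is expression of the NR5A1 construct without doxycycline, which these values cannot separate from the endogenous gene.

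For the 3 comparisons of replicated groups, the counts of genes past the threshold were 9004, 11567 and 10020, and the highest counts of the other splits of the same 6 libraries were 1, 3 and 4. In each, 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.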

How the results depend on the processing

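The tests with limma-voom, with the length and GC trend removed, with the line term for NR5A1-CHIR against parental TF or together with rescaling, with the parental libraries split, and every test of the EOS pair alternatives, of EOS-TF against parental TF and of the interaction were chosen only after the results were seen. Over 26 results, 299 values were computed under alternatives. Of these, 256 stayed within the bound set for them, such as 1.5 times for a count, and 43 moved further. Only the log2 change of NR5A1, the list positions and the score differences could change sign, and 0 of them did. Each count of higher or lower genes was judged alone, so a turned balance could lie within the bound. Requiring a log2 change of at least 1 gave 1327 genes higher and 1713 lower for NR5A1-CHIR against parental TF, 2853 and 3221 for tt2iLGöX against parental TF, 1955 and 2049 for tt2iLGöX against NR5A1-CHIR, and 908 more positive in the interaction. The line term gave 3113 higher and 5512 lower, and 2799 and 4573, for the tt2iLGöX comparisons with parental TF and NR5A1-CHIR. Together with median-ratio rescaling it gave 4351 higher and 4098 lower, and 3570 and 3604, so rescaling moved the balance of higher and lower genes. Higher calls shared with the main fit went from 2848 to 3669 and from 2452 to 2930 when rescaling was added. Shared lower calls went from 4563 to 3693 and from 3540 to 3007, with the cause not tested. For EOS-reset against tt2iLGöX, the 3 genes became 13 with a pseudocount of 0.1, 47 without a filter, 19 with array weights and 0 with limma-voom, where 897 genes had an unadjusted p under 0.05. In the limma test on log2(TPM + 1) that number was 846. Both numbers lie near the share of 0.05 of the tested genes that would be seen without any difference. The cause of the changed counts was not tested. The smaller pseudocount put NR5A1-CHIR at 41.6% of the way on the naive list and widened the score differences to 2.97 and 7.12 on the naive and -1.57 and -4.81 on the primed list, as it stretches low values by construction. Without a filter the naive difference of tt2iLGöX was 5.52, since a list gene of low level enters. With EOS-TF as control, 1387 genes were higher in both groups, and with parental library 2 for NR5A1-CHIR and the others for tt2iLGöX 1801 were; the cause was not tested. In the EOS pair, the share of genes with the sign of NR5A1-CHIR was 71.1% for higher and 75.5% for lower genes after median-ratio rescaling, 68.3% and 77.3% after quantile normalization, and 78.6% for lower genes without a filter; the cause was not tested. With camera 10, 5, 7 and 7 lists passed in the 3 replicated comparisons and EOS-reset; with an estimated correlation 0 did in all 4, and with fry 18, 20, 15 and 0.

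Leaving out each library in turn gave, for NR5A1-CHIR against parental TF, 3465 to 3917 genes higher and 4198 to 4510 lower; for tt2iLGöX against parental TF, 5042 to 5492 and 5712 to 6026; and for tt2iLGöX against NR5A1-CHIR, 4599 to 5072 and 4446 to 4949. EOS-reset gave 3 to 68, with 68 without tt2iLGöX library 1 and 14 without library 3. The interaction gave 938 to 1391 and 763 to 1164. Shared higher genes were 2368 to 3029 and shared lower genes 3142 to 3797. The log2 change of NR5A1 was 5.01 to 5.14, and 5.09 to 6.67 over the other settings. The naive position was 35.3% to 36.6% and the primed position 32.9% to 35.1%. The naive score differences were 2.01 to 2.10 and 5.63 to 5.82, and the primed ones -1.35 to -1.26 and -3.88 to -3.79. No paired analysis was possible because the columns carry no replicate numbers, so the planned replicate block was not run. Depth limited genes of low level: 3 reads were worth 0.182 to 0.296 TPM at the median gene.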

Other observations

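The tests of successive steps and the spread of trophoblast markers were chosen only after the results of the comparisons were seen. Cholesterol biosynthesis genes rose together in NR5A1-CHIR: 14 of 18 were higher than in parental TF and 0 lower (the same adjusted over the list alone, camera adjusted p = 1.79e-06, adjusted p = 0.369 with an estimated correlation). The enzyme genes MVK (1.93 ± 0.11), LSS (1.46 ± 0.14) and NSDHL (1.42 ± 0.09) rose. In tt2iLGöX against parental TF 10 were higher and 4 lower (the same adjusted over the list alone, camera adjusted p = 0.208, adjusted p = 0.785 with an estimated correlation). With a line term 5 were higher and 6 lower. Against NR5A1-CHIR, 10 were lower and 1 higher (the same adjusted over the list alone, camera adjusted p = 0.0142, adjusted p = 0.729 with an estimated correlation). SC5D (-2.01 ± 0.11), IDI1 (-1.77 ± 0.10), HMGCS1 (-1.24 ± 0.16) and CYP51A1 (-1.19 ± 0.09) were down. Genes of the integrated stress response fell in NR5A1-CHIR, 10 of 18 with 1 higher (the same adjusted over the list alone, camera adjusted p = 0.00812, adjusted p = 0.463 with an estimated correlation). Among them were VLDLR (-1.73 ± 0.13), ASNS (-1.44 ± 0.12) and ATF3 (-1.39 ± 0.14, not past the test with a line term and rescaling). With a line term 4 were lower and 1 higher, and the EOS pair went the other way, with a list median of 0.48 against -0.39. In tt2iLGöX 12 were higher than in NR5A1-CHIR and 2 lower (the same adjusted over the list alone, camera adjusted p = 0.0105, adjusted p = 0.729 with an estimated correlation). TRIB3 (3.04 ± 0.14), DDIT3 (1.90 ± 0.20), ATF5 (1.77 ± 0.15) and SESN2 (1.67 ± 0.13) were up; with a line term 7 were higher and 1 lower. Against parental TF they split 8 and 7 (the same adjusted over the list alone, camera adjusted p = 0.746, adjusted p = 0.931 with an estimated correlation), and 6 and 2 with a line term.

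Of 16 p53 targets, 8 rose in NR5A1-CHIR and 0 fell (the same adjusted over the list alone, camera adjusted p = 0.00754, adjusted p = 0.463 with an estimated correlation). The cell cycle inhibitor gene CDKN1A (2.17 ± 0.31) and the p53 ligase gene MDM2 (1.60 ± 0.13) rose most. In tt2iLGöX against parental TF 12 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.0645, adjusted p = 0.716 with an estimated correlation), FAS (-2.28 ± 0.19) among the latter; with a line term 8 rose and 3 fell. Of 18 G2/M genes, 12 fell and 2 rose in NR5A1-CHIR (the same adjusted over the list alone, camera adjusted p = 0.0135, adjusted p = 0.463 with an estimated correlation), with TOP2A (-1.15 ± 0.09) and CDK1 (-1.07 ± 0.10) down. In tt2iLGöX against parental TF 9 fell and 6 rose (the same adjusted over the list alone, camera adjusted p = 0.597, adjusted p = 0.878 with an estimated correlation), with CENPE (-2.23 ± 0.19) down and PLK1 (1.42 ± 0.11) up, and 5 down and 3 up in all with a line term. Glycolysis genes split 7 higher and 5 lower of 20 in NR5A1-CHIR (the same adjusted over the list alone, camera adjusted p = 0.373, adjusted p = 0.639 with an estimated correlation). Of the same genes 10 were higher and 7 lower in tt2iLGöX than in parental TF (the same adjusted over the list alone, camera adjusted p = 0.430, adjusted p = 0.761 with an estimated correlation), or 7 and 8 with a line term. The glucose transporter gene SLC2A3 fell (-3.32 ± 0.22) and the lactate exporter gene SLC16A3 rose (2.77 ± 0.30). Against NR5A1-CHIR, PDK1, a kinase that inhibits pyruvate dehydrogenase, was lower in tt2iLGöX (-2.63 ± 0.10). Oxidative phosphorylation genes split 13 higher and 4 lower of 33 in NR5A1-CHIR (the same adjusted over the list alone, camera adjusted p = 0.148, adjusted p = 0.468 with an estimated correlation). From parental TF to tt2iLGöX 19 rose and 7 fell (the same adjusted over the list alone, camera adjusted p = 0.121, adjusted p = 0.600 with an estimated correlation). With a line term 20 rose and 1 fell. The largest changes had COX7B (1.08 ± 0.07) and COX5A (1.10 ± 0.09) up and COX7C (-1.34 ± 0.08) down, and COX7C did not pass with a line term and rescaling. Replication histones, whose transcripts lack a poly(A) tail, were measured as well: 1 rose and 2 fell of 13 in NR5A1-CHIR (the same adjusted over the list alone, camera adjusted p = 0.811, adjusted p = 0.893 with an estimated correlation). From parental TF to tt2iLGöX 0 rose and 9 fell (the same adjusted over the list alone, camera adjusted p = 0.121, adjusted p = 0.583 with an estimated correlation).

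Taking the change to NR5A1-CHIR as a first step and that from NR5A1-CHIR to tt2iLGöX as a second, 1587 genes were higher in both steps, DPPA5, KLF4 and DNMT3L among them. Another 1732 were lower in both, DUSP6, VIM and CDH2 among them. A further 1414 were higher and then lower, as KRBOX1, LEFTY2, SKIL and AXIN2 were. The opposite held for 1356, lower and then higher, as SFRP1, ADM and OTX2 were. Independent lists of these sizes would give 1345, 1560, 1321 and 1589. The covariance of both steps was -0.0601, against -0.0198 in simulated unchanged groups, which share the NR5A1-CHIR libraries with opposite sign. Pearson r was -0.0584 against a simulated -0.498. The simulated r describes groups without change, and real changes dilute it, so the r values are not comparable. On the covariance scale the value was more negative than in the simulation. With the EOSN1-CHIR library as the start of the second step, the 4 counts were 896, 1591, 1294 and 829, where independent lists would give 787.7, 1411, 1194 and 930.4.

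Trophoblast markers varied more among the tt2iLGöX libraries than in other groups: CGA stood at 8.78 ± 9.78 TPM, VGLL1 at 7.14 ± 8.74 TPM and GATA3 at 11.9 ± 11.8 TPM. Library 1 stood apart, with a list score of 4.09 against 3.00 and 3.09, and much of the spread and of the rise came from it. The list score was 3.39 ± 0.61 (SD, n = 3) against 2.58 ± 0.05 in parental TF, 2.75 ± 0.05 in NR5A1-CHIR and 2.91 in EOS-reset.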
